A study of Oryza sativa with 12 samples.

How the data were processed

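The series holds RNA-seq of rice (Oryza sativa, subspecies Indica), cultivar Pusa Basmati 1, a basmati variety. Per the labels, total RNA was taken with Trizol from roots of 14-day-old seedlings and from seedlings, and libraries followed standard Illumina protocols. The labels list 12 libraries, 2 for each of 6 groups, which cross the 2 tissues with nitrogen at 0 mM (low nitrogen stress), 10 mM (the control) and 100 mM (high nitrogen stress). The second tissue is called seedlings throughout, as the labels give it, and whether its samples included roots is not stated there.

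The values analysed here are gene-level FPKM, fragments scaled by transcript length and by mapped fragments, per the file headers, as deposited by the authors. Per the submitters' processing notes the tools were cutadapt, HISAT2, Cufflinks 2.2.1 and Cuffdiff, named without their roles. The genome build, the annotation and the way the libraries of a group were combined are not given in the sources used here. There was 1 table for roots and 1 for seedlings, each with the same 36843 features and 1 FPKM column per nitrogen level. Each value is therefore the authors' value for a group, with no value per library.

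This decides what can be said. No spread between replicates can be computed, so no value carries an SD and no difference has a replicate check. The limma tests planned before the data were examined, with their interaction contrasts and gene set tests, could not be run, and rules of size took their place, as the plan foresaw for pooled values. The depth is unknown: values run down to 1.00e-07 FPKM in the 10 mM roots column without steps of whole reads, so neither counting intervals nor detection limits are given. A gene at exactly 0 is called listed at 0, and no fold is given against it.

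Changes are differences of log2(FPKM + 1) between group values, within a tissue. The pseudocount of 1 understates the change of low genes. Features with a mean of at least 1 FPKM over the 3 columns of a tissue were kept (21558 in roots, 22186 in seedlings), and a gene was counted as higher or lower at an absolute log2 change of at least 1. The 2 tables may have been normalized separately, so changes were computed within each table and levels set across tables carry that caveat. For the tissues, genes were counted whose changes differed by at least 2 on the log2 scale. Comparisons of 0 mM and of 100 mM with 10 mM share the control column.

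Before the data were examined, 30 gene lists were fixed from identifiers and name patterns. Of 61 fixed identifiers 59 were in the tables, and 3 lists matched no name in the tables and are not analysed here. A further 53 pattern matches that named another gene family were dropped by name alone, among them uclacyanins matched by a regulator pattern. A list with at least 5 kept members was described by the percentile of its median change among 10000 random lists of the same size, matched on mean expression in 20 bins with random seed 1. Percentiles under 2.5 or over 97.5 are called outside the range of random lists. They describe these columns and are not p-values, since genes are not replicates. Lists for metallothioneins, intrinsic protein aquaporins and genes named nitrate transporter were added after the names in the tables had been seen.

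The genes named in the text follow a rule fixed beforehand. For each comparison with 10 mM it takes the 6 largest rises and the 6 largest falls among genes with a descriptive name and at least 5 FPKM in the higher group, 19 genes of nitrogen uptake and assimilation (18 were found), and up to 4 members of each list past the threshold of size. For the difference between tissues it takes the 4 genes with the largest difference. The parts of the rule that need p-values or single libraries were replaced by the size of the change, and short structural RNA features were left out of the naming after they had been seen. Symbols such as NR2 or NRT2.3 were fixed with the identifiers, and all other names are the short names in the tables, which 10796 of the features carry. Near-identical copies (NRT2.1 and NRT2.2, NIA1 and NIA2, NAS1 and NAS2, the chlorophyll a/b binding protein, Rubisco small subunit and metallothionein genes) may share reads, so how their signal is divided is uncertain.

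The procedure was tested on simulated data. In a simulated comparison of 0 mM with 10 mM in roots over 21544 genes, with noise of 0.2 on the log2 scale, 100% of 200 genes changed 4-fold were recovered, and 1 unchanged gene was called. In the same simulation for seedlings over 22154 genes, 100% were recovered with 4 unchanged genes called. Of 100 random unchanged lists, 1 in the roots simulation and 3 in the seedlings simulation lay outside the range. The noise was assumed, not measured, and independent between genes, so the unchanged lists say nothing about genes that vary together. With so little noise against a threshold of 1, the recovery and the few false calls followed from the setting. They give no error rate for these data. The SD across genes of the observed changes at 0 mM, real changes included, was 0.50 in roots and 0.53 in seedlings. The changed genes were drawn from those with at least 5 FPKM at 10 mM, so the recovery of lower genes was not tried.

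Alternatives were a pseudocount of 0.1 or 5, no filter on low values, a mean of at least 5 FPKM, median-of-ratios rescaling and quantile normalization within a tissue. Restricting the counts to features with a short name, and quantile normalization for the gene lists and for genes past the threshold at both nitrogen levels, were added after the data were seen. Computations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9. All 6 value columns were used.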

Results

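Transcript levels were measured in roots and in seedlings of Pusa Basmati 1 rice at 14 days, grown with 0, 10 or 100 mM nitrogen. Each tissue was represented by 3 columns of FPKM values, 1 per nitrogen level, each the authors' value for a group of 2 libraries. No value therefore has an error or n of its own, and none of the differences below was tested against the spread between replicates. The columns summed to between 690853 FPKM (seedlings, 100 mM) and 737552 FPKM (seedlings, 10 mM), and between 6874 and 8359 of the 36843 features were listed at 0 in a column. Across genes kept in a tissue, log2(FPKM + 1) of any 2 columns correlated with r between 0.94 and 0.96. The comparisons of 0 mM and 100 mM with 10 mM address which genes respond to low and to high nitrogen in each tissue, including those of nitrate uptake and assimilation.

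In roots at 0 mM, 3 of 4 genes of nitrate reduction and 3 of 9 of ammonium assimilation were lower than at 10 mM, and none of either list was higher. NR2 (Os02g0770800, chromosome 2, 32513748 to 32517155 as the table gives it), a nitrate reductase, stood at 7.80 FPKM against 51.7, a log2 change of -2.58. NiR1 (Os01g0357100, chromosome 1, 14446912 to 14453462), a nitrite reductase, stood at 24.1 against 111 FPKM, and AS1 (Os03g0291500), an asparagine synthetase, at 24.8 against 151 FPKM. The high-affinity nitrate transporter NRT2.3 (Os01g0704100, chromosome 1, 29188849 to 29190936) was higher, at 155 against 23.3 FPKM (log2 change 2.68). Of 7 iron acquisition genes 5 were lower, with nicotianamine synthases NAS1 and NAS2 at 15.6 against 230 FPKM and at 12.6 against 209 FPKM.

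By the threshold of size 395 genes were higher and 652 lower at 0 mM in roots, of 21558 kept, and the median change of all kept genes was 0.06. The nitrate reductase NIA1 was at 8.45 against 14.2 FPKM. The ammonium assimilation genes that were lower were AS1, GS1;2 and GS2, with a list median of -0.64 below every random list (percentile 0). GS1;2 was at 136 against 330 FPKM, while GS1;1 was at 1042 against 732 FPKM, short of the threshold. Among the nitrate regulators, the repressor NIGT1 was at 0.754 against 7.0 FPKM and the lateral organ boundaries domain gene LBD38 (Os03g0609500) at 9.89 against 48.0 FPKM, while NLP1 was at 22 against 8.84 FPKM. The 8 genes of that list did not move together (median 0.13, percentile 72.4). Other nitrate and ammonium transporters diverged. NRT2.1 was at 5.97 against 27.5 FPKM, NRT1.1B at 9.26 against 36.1 FPKM and AMT1;3 at 8.81 against 27.8 FPKM, while NPF2.2 was at 14.4 against 4.85 FPKM. NRT2.2, NAR2.1, AMT1;1, AMT1;2, Fd-GOGAT and NADH-GOGAT2 lay within the threshold.

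The iron acquisition list had a median of -2.74, below the random range of -0.22 to 0.32. YSL15, an iron-phytosiderophore transporter, was at 3.87 against 65.4 FPKM, and the bHLH gene IRO2 at 4.02 against 32.6 FPKM. Of 46 phenylpropanoid genes 13 were higher and 1 lower (median 0.43, percentile 100), led by putrescine hydroxycinnamoyl transferase 2 at 83.8 against 12.4 FPKM, hydroxycinnamoyltransferase 4 at 305 against 79.6 FPKM and a chalcone isomerase at 93.3 against 24.7 FPKM. Of 30 defence genes 9 were lower and 2 higher (median -0.66, percentile 0), among them chitinase 1 (Os10g0416500) at 1.54 against 48.6 FPKM. Of 22 genes of light harvesting and the photosystems 21 were lower (median -1.66, percentile 0), at low levels: chlorophyll a/b binding protein 1R was at 5.10 against 46.9 FPKM. The leaf markers in roots stood at a median of 0.715% of their seedling level at 10 mM, set across tables that may be scaled differently. The largest changes by the naming rule included hemoglobin 2 (Os03g0226200), at 28.0 against 706 FPKM, the F-box gene Kiss Me Deadly 2 at 0.789 against 30.3 FPKM, and allantoinase, an enzyme of ureide breakdown, at 30.4 against 2.67 FPKM. A thionin (Os06g0509900) with 14.7 FPKM at 10 mM was listed at 0. Ethylene response factors 103 and 104 were at 7.56 against 0.548 and at 7.15 against 0.450 FPKM, and cis-zeatin O-glucosyltransferase 2 at 7.14 against 0.530 FPKM.

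Of 22 lists with a percentile, 13 lay outside the range of random lists in this comparison. Random lists would give about 1.1, but members of a list may vary together and lists overlap, so no chance level is read from it. The leaf markers, a list that contains the light-harvesting genes, had 22 of 24 lower (median -1.63). The other lists outside the range were phosphate starvation (median -0.27), reductant supply (-0.50, with a ferredoxin-NADP+ reductase at 108 against 297 FPKM), late embryogenesis abundant proteins (-0.27, percentile 15.8 without the filter on low values), class III peroxidases (-0.16), glutathione transferases (-0.26, 9 of 59 lower), expansins (-0.13) and heat shock genes (0.16). The NPF transporters, ammonium transporters, root markers, chlorophyll synthesis, glutaredoxins, senescence and autophagy, starch and sugar, and WRKY lists lay inside it.

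In seedlings at 0 mM all 4 measured genes of nitrate reduction and 6 of 8 of chlorophyll synthesis were lower. NiR1 was at 6.85 against 49.8 FPKM, NIA1 at 0.686 against 8.19 FPKM, NR2 at 2.32 against 11.6 FPKM and AS1 at 14.0 against 80.3 FPKM. NRT2.3 was again higher, at 39.4 against 7.68 FPKM. Protochlorophyllide oxidoreductase A (Os04g0678700), an enzyme of chlorophyll synthesis, was at 51.3 against 574 FPKM. Ribonuclease 4 (Os09g0537700) and ribonuclease 5 (Os09g0538000), whose identifiers are close, were at 0.0775 against 104 FPKM and at 0.488 against 65.1 FPKM, log2 changes of -6.61 and -5.47.

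In total 754 genes were higher and 412 lower at 0 mM in seedlings, of 22186 kept, so 64.7% of the counted genes were higher. That share was 53.3% after median-of-ratios rescaling, which takes about 0.09 from the changes of high genes, and 51.3% after quantile normalization. NIGT1 was at 0.982 against 4.16 FPKM and LBD38 at 2.77 against 15.5 FPKM. NRT2.1 was at 1.58 against 5.46 FPKM, the NRT2 activator NAR2.2 at 4.12 against 0.919 FPKM, and NRT1.1B at 49.1 against 22.1 FPKM. Of 10 ammonium assimilation genes only AS1 passed the threshold, and the list median was -0.46 (percentile 0.210). The chlorophyll synthesis list had a median of -1.53 (percentile 0), with magnesium chelatase subunit ChlH at 14.0 against 98.6 FPKM and glutamyl-tRNA reductase at 46 against 158 FPKM. Of 23 light-harvesting and photosystem genes 8 were lower and none higher (median -0.79, percentile 0). Chlorophyll a/b binding protein 2R was at 994 against 6666 FPKM and CP29 at 765 against 3224 FPKM. Quantile normalization left 7 of the 23 lower with a median of -0.17, inside the random range (percentile 9.95). The 3 Rubisco small subunit genes lay within the threshold (median 0.29).

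Of 47 phenylpropanoid genes in seedlings 12 were higher and none lower (median 0.49, percentile 100), among them cinnamyl alcohol dehydrogenase 6 at 30.8 against 8.61 FPKM. Of 67 genes for WRKY transcription factors 15 were higher and 1 lower (median 0.40, percentile 100), with WRKY71 at 18.4 against 5.48 FPKM and WRKY67 at 76.9 against 26.0 FPKM. Of 34 defence genes 9 were lower and 3 higher (median -0.52, percentile 0, but 0.01 and percentile 39.0 without the filter on low values), with chitinase 4 at 7.30 against 34.0 FPKM and pathogenesis-related gene 10B at 23.8 against 7.80 FPKM. Iron acquisition genes had a median of -0.63 (percentile 0.0300), with 2 of 7 lower (NAS1 and NAS2), and expansins one of -0.17. Senescence associated gene 12-1 (Os01g0907600) was at 36.4 against 0.633 FPKM, the largest rise by the naming rule, and cysteine protease 1 at 10.7 against 0.333 FPKM, while the senescence and autophagy list as a whole lay inside the random range (percentile 38.5). Alpha-amylase 10-C was at 14.0 against 0.766 FPKM and alpha-amylase 1A at 205 against 49.5 FPKM. Metallothioneins 3B, 1G and I-4B were at 89.9 against 6.65, 138 against 16.0 and 91.8 against 12.3 FPKM. Hemoglobin 2 was lower here too, at 14.4 against 165 FPKM, as was a CBS domain chloride channel gene (Os12g0438600) at 3.19 against 36.1 FPKM and xylanase inhibitor protein 2 (Os05g0247100) at 21.8 against 192 FPKM. Of 23 lists 9 lay outside the random range (about 1.15 for random lists, with the same limit as in roots). After quantile normalization 7 did, as it brought the light-harvesting and leaf marker lists inside. Without the filter on low values class III peroxidases (percentile 2.26) and late embryogenesis abundant proteins (1.48) lay outside it too. Root marker genes moved by a median of 0.28, inside the range, and none of 6 passed the threshold. The seedling level relative to roots, set across the 2 tables, was higher at 0 mM than at 10 mM for Lsi1 (32.4% against 17.8%), Lsi2 (33.0% against 19.7%) and RCc3 (30.3% against 21.5%). The other 3 of the list, silicon efflux transporters 3, 4 and 5, singled out after their values were seen, stood in seedlings at 91.5%, 145% and 2279% of their root level at 10 mM, so they do not mark roots here.

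**Figure D1:**
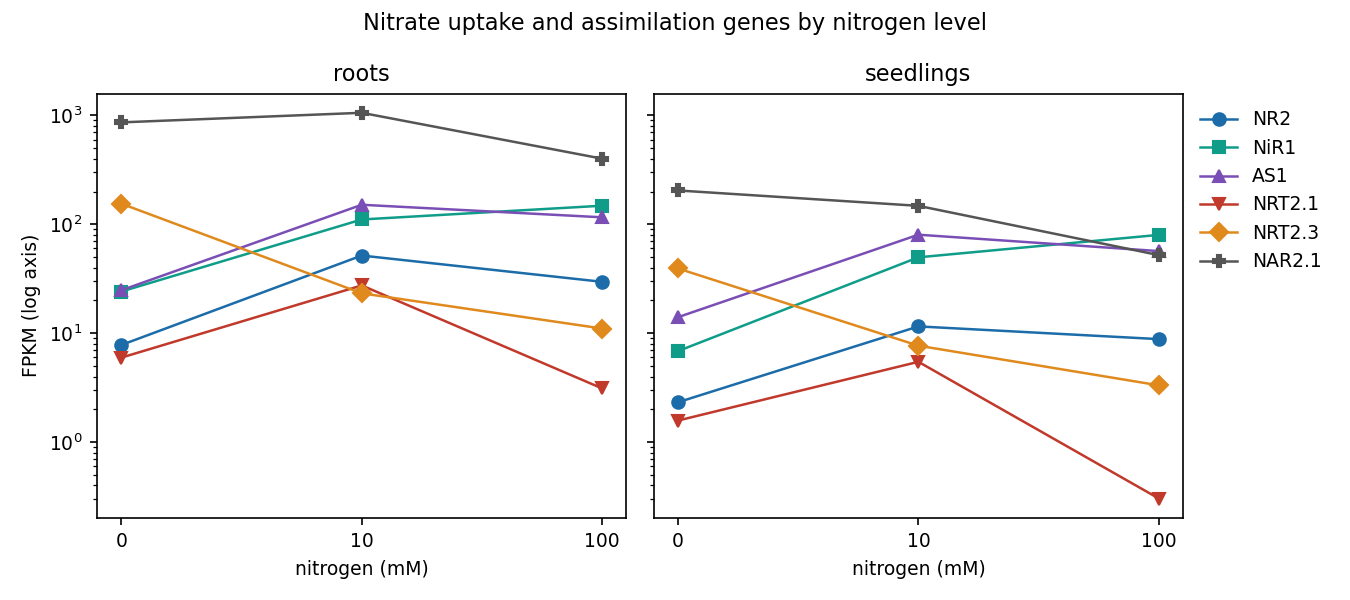
FPKM (log axis) of 6 nitrate uptake and assimilation genes against nitrogen level (0, 10 and 100 mM, evenly spaced) in roots (left) and seedlings (right), where each point is the authors' value for a group and lines only join the points of a gene. NR2, NiR1 and AS1 were lowest at 0 mM in both tissues, NRT2.3 was highest at 0 mM (155 and 39.4 FPKM), and NRT2.1 was lowest at 100 mM (3.11 and 0.303 FPKM).

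In roots at 100 mM, all 4 measured genes of high-affinity nitrate uptake and 6 of 7 of iron acquisition were lower than at 10 mM, while nitrate reduction genes stayed within the threshold. NRT2.1 was at 3.11 against 27.5 FPKM, NRT2.2 at 2.51 against 16.4 FPKM, NRT2.3 at 11.0 against 23.3 FPKM and their partner NAR2.1 at 401 against 1058 FPKM. The largest rises by the naming rule were nitrate transporter 1.5B (Os02g0716800) at 46.6 against 0.256 FPKM and UNP1 (Os04g0627900) at 80.0 against 2.60 FPKM. The cytosolic glutamine synthetase GS1;3 was at 14.1 against 0.798 FPKM. NAS1 was at 11.5 against 230 FPKM and the mugineic acid transporter TOM1 (Os11g0134900) at 1.37 against 30.4 FPKM.

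By the threshold 401 genes were higher and 505 lower, so 44.3% of the counted genes were higher, and 33.2% after median-of-ratios rescaling, which takes about 0.12 from the changes of high genes. NR2 was at 29.7 against 51.7 FPKM, NiR1 at 148 against 111 FPKM and AS1 at 116 against 151 FPKM. GS1;2 was lower (98.3 against 330 FPKM), as were AMT1;3 (11.1 against 27.8 FPKM) and NRT1.1B (12.7 against 36.1 FPKM), while NIGT1 was higher (16.2 against 7.0 FPKM). The iron acquisition list had a median of -2.68 (random range -0.20 to 0.33), with YSL15 at 5.07 against 65.4 FPKM and IRO2 at 4.24 against 32.6 FPKM. A peptide transporter family gene (Os01g0871600) was at 1.81 against 31.8 FPKM, in an NPF list with a median of -0.80 (percentile 0.0200), and ammonium transporters had a median of -0.23. Of 63 WRKY genes 6 were lower and 3 higher, with a median of -0.11 below the random range of 0.01 to 0.20. WRKY76 was at 0.475 against 11.8 FPKM, WRKY62 at 3.55 against 19.7 FPKM and WRKY31 at 31.4 against 9.14 FPKM. Of 22 light-harvesting and photosystem genes 6 were lower (median -0.27, percentile 0), those named being the chlorophyll a/b binding proteins and CP24. Class III peroxidases (median -0.07) and the leaf marker list (-0.27) were the other lists outside the range, 7 of 22 in all.

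In roots at 100 mM the starch and sugar list (4 of 38 lower, 1 higher) and the defence list (6 of 30 lower, 4 higher) lay inside the random range, but the defence list lay below it without the filter on low values (percentile 0.870). Cell-wall invertase 5 (Os04g0664900) was at 8.88 against 40.4 FPKM, the sugar transporter SWEET4 at 17.3 against 47.0 FPKM, chitinase 1 at 6.70 against 48.6 FPKM and pathogenesis-related gene 1A (Os07g0129200) at 20.4 against 91.8 FPKM. Of 46 phenylpropanoid genes 5 were lower and 2 higher, hydroxycinnamoyltransferase 4 being at 14.8 against 79.6 FPKM. Late embryogenesis abundant protein 9 (Os01g0314800) was higher, at 457 against 143 FPKM, as were phi glutathione S-transferase 12 (32.7 against 7.51 FPKM) and class III peroxidase 95 (150 against 42.6 FPKM). The silicon transporters Lsi1 and Lsi2, root markers, were at 267 against 709 and at 131 against 284 FPKM. Further large rises by the rule were uclacyanin-like protein 35 at 137 against 16.1 FPKM, lipid transfer protein d6 at 136 against 19.2 FPKM and a UDP-glucosyltransferase (Os04g0206600) at 9.57 against 0.106 FPKM.

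In seedlings at 100 mM, 20 of 23 light-harvesting and photosystem genes were lower, while 21 of 67 WRKY and 15 of 34 defence genes were higher and the rest of these 2 lists within the threshold. Chlorophyll a/b binding protein 2R was at 313 against 6666 FPKM, 1R at 260 against 4487 FPKM and CP26 at 117 against 2647 FPKM. The Lhcb2 gene (Os03g0592500), which is not a member of that list, was at 276 against 5422 FPKM. WRKY71 was at 54.9 against 5.48 FPKM, WRKY7 at 25.9 against 2.05 FPKM and pathogenesis-related 1a (Os07g0129300) at 16.9 against 0.926 FPKM. NRT2.1, NRT2.2, NRT2.3 and NAR2.1 were lower, as in roots, and root RNA in the seedling samples may contribute to this.

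Here 1348 genes were higher and 451 lower, 74.9% of the counted genes being higher. The median change of all kept genes was 0.17. Median-of-ratios rescaling takes about 0.21 from the changes of high genes and less from those of low ones. It gave 892 higher and 688 lower (56.5% higher), and quantile normalization gave 57.2% higher. The light-harvesting and photosystem list had a median of -1.85 (random range -0.25 to 0.18). The count of lower genes was 20 after rescaling too, and 13 with a median of -1.03 after quantile normalization. In the same comparison 6 of 11 core clock genes, many of which vary with the time of day, passed the threshold, and 2 did at 0 mM. Of 8 chlorophyll synthesis genes 6 were lower (median -1.47, percentile 0), with protochlorophyllide oxidoreductase A at 52.7 against 574 FPKM and ChlH at 12.7 against 98.6 FPKM. The 3 Rubisco small subunit genes lay within the threshold, with a median of -0.13. The WRKY list had a median of 0.61 (random range 0.07 to 0.30, 18 genes higher after rescaling, 9 below 0) and the defence list one of 0.93 (random range 0.03 to 0.35, 13 genes higher after rescaling), the latter including a thaumatin gene, Tolerance Of Nitrogen Deficiency 1, at 26.4 against 2.74 FPKM and chitinase 8 at 80.0 against 13.7 FPKM. Without the filter on low values the defence median was 0.24. Of 60 glutathione transferases 11 were higher and none lower (median 0.37, percentile 99.9), but 4 were higher after rescaling.

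Among nitrogen genes in seedlings at 100 mM, NRT2.1 was at 0.303 against 5.46 FPKM and NAR2.1 at 52.1 against 148 FPKM, and 4 of 5 genes of that list were lower (median -1.49, percentile 0). NIGT1 was at 14.7 against 4.16 FPKM and GS1;3 at 4.60 against 0.507 FPKM. GS1;2 (40.0 against 95.2 FPKM) and NADH-GOGAT2 (26.1 against 71.2 FPKM) were lower. NiR1, at 80.0 against 49.8 FPKM, and Fd-GOGAT, at 98.5 against 53.2 FPKM, lay within the threshold. NAS1, NAS2 and YSL15 were lower (25.1 against 71.3, 24.8 against 60.9 and 6.40 against 17.4 FPKM), 3 of 7 genes in a list with a median of -0.42 (percentile 0.240). Phosphate starvation genes had a median of 0.39 (percentile 98.2). UNP1 was at 33.8 against 0.783 FPKM, uclacyanin-like protein 29 at 42.9 against 1.61 FPKM, and a DREB1A transcription factor gene (Os09g0522200) at 54.8 against 2.33 FPKM. Isocitrate lyase, an enzyme of the glyoxylate cycle, was at 26.5 against 1.02 FPKM, and late embryogenesis abundant protein 9 at 310 against 36.5 FPKM. DnaJ domain protein C10 (Os01g0606900) was at 0.775 against 42.4 FPKM, the largest fall by the rule. Senescence associated gene 12-1 was at 20.3 against 0.633 FPKM. The leaf markers, which contain the light-harvesting genes, had a median of -1.66 and were the last of 9 of 23 lists outside the range. The lists for cytosolic ribosomal proteins, the Calvin cycle and cytokinin had at most 2 kept members, none past the threshold against 10 mM in either tissue. The remaining lists lay inside the range, among them phenylpropanoid genes (0.18), class III peroxidases (0.09), heat shock genes (0.06) and glutaredoxins (0.07), whose medians turn negative under median-of-ratios rescaling. The calls of 2 further lists inside it depended on the setting: expansins lay below the range after that rescaling (percentile 1.70) and without the filter on low values (1.995), and late embryogenesis abundant proteins above it without the filter (99.82).

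**Figure D2:**
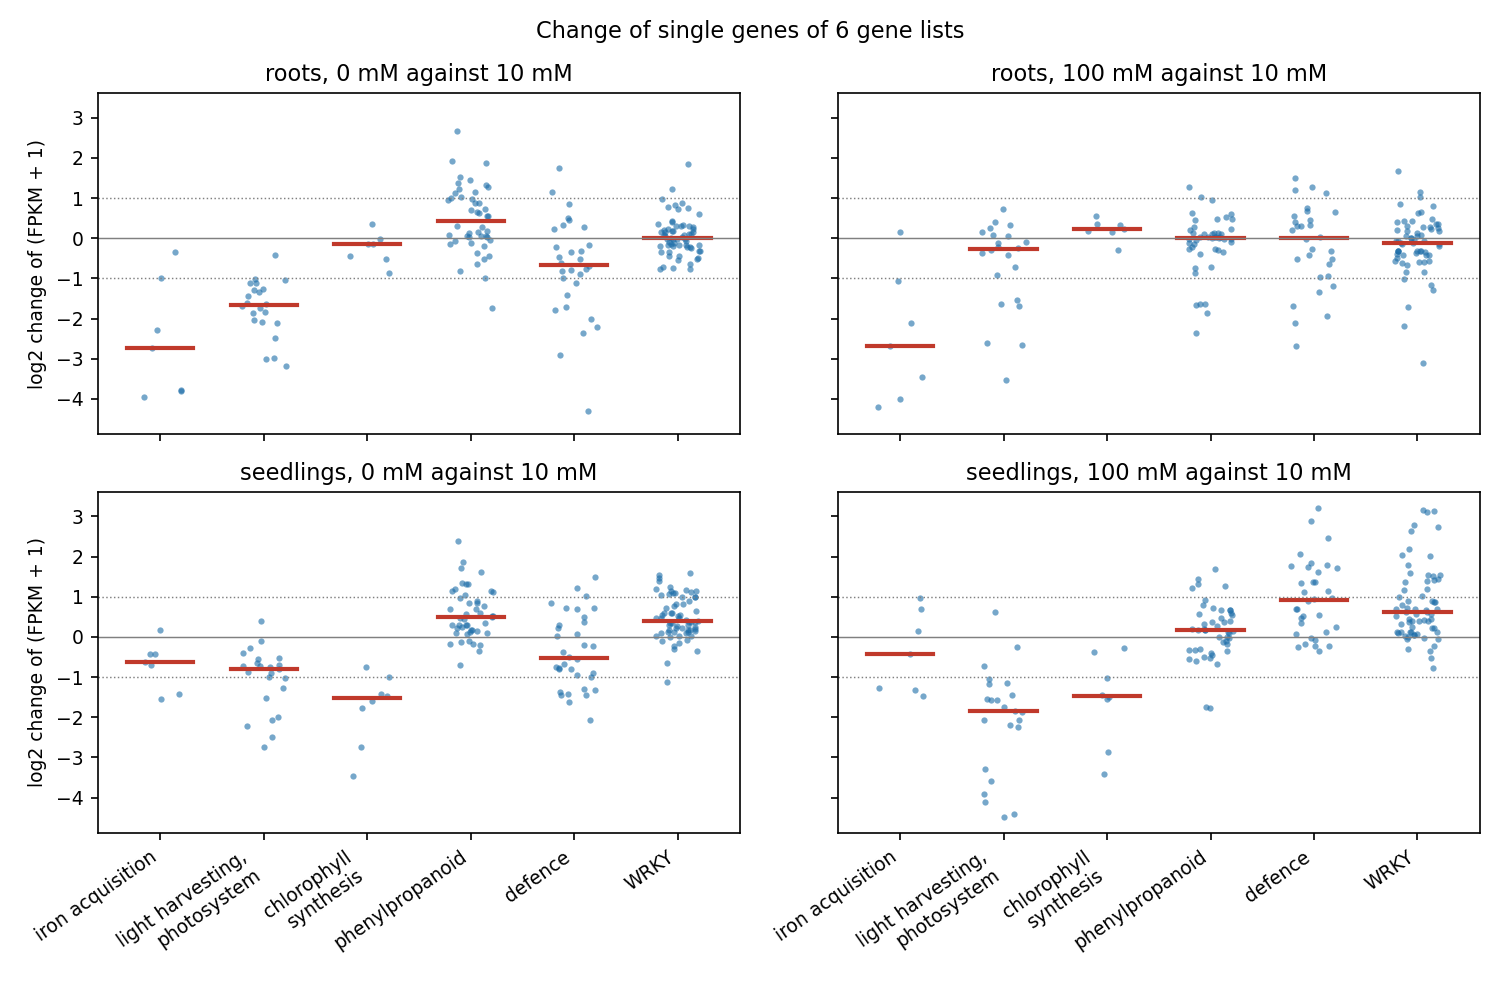
Log2 change of FPKM + 1 against 10 mM for each kept member (points, spread sideways at random) of 6 gene lists fixed before the data were examined, in roots (top) and seedlings (bottom) at 0 mM (left) and 100 mM (right); red bars are list medians and dotted lines the threshold of 1. Iron acquisition had medians of -2.74 and -2.68 in roots, light harvesting -1.85 in seedlings at 100 mM, and defence 0.93 in seedlings at 100 mM.

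Between 100 mM and 0 mM, 930 genes were higher and 774 lower at 100 mM in roots, and 919 higher and 715 lower in seedlings. In seedlings the share of higher genes was 56.2%, and 45.3% after median-of-ratios rescaling, so the majority changed side under a shift of about 0.12 for high genes. Among the nitrogen genes, NRT2.3 was at 11.0 FPKM at 100 mM against 155 at 0 mM in roots (log2 change -3.70) and at 3.32 against 39.4 in seedlings (-3.22). NiR1 was at 148 against 24.1 FPKM in roots (2.57) and at 80.0 against 6.85 FPKM in seedlings (3.37), and AS1 at 116 against 24.8 FPKM in roots (2.18) and at 56.8 against 14.0 FPKM in seedlings (1.94). NAR2.1 was at 401 against 864 FPKM in roots and 52.1 against 205 FPKM in seedlings. AMT1;2 was at 2.18 against 5.65 FPKM in roots. NRT2.4 was listed at 0 in both tissues at 100 mM. Of the lists, phenylpropanoid genes were lower at 100 mM than at 0 mM in both tissues, 14 of 46 in roots (median -0.41) and 10 of 47 in seedlings (median -0.41), each with 2 higher. Of 34 defence genes in seedlings 19 were higher and none lower (median 1.36). Light-harvesting and photosystem genes went opposite ways as a list, 11 of 22 higher in roots (median 1.01) and 13 of 23 lower in seedlings (median -1.02). This difference between tissues was not tested. The 11 in roots were photosystem subunits at low levels, such as a photosystem II subunit (Os01g0501800) at 40.2 against 9.31 FPKM. None of the list's chlorophyll a/b binding proteins, CP24, CP26 or CP29 passed the threshold in roots, and 1R was at 3.15 against 5.10 FPKM.

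The genes past the threshold in roots and in seedlings overlapped. Of 20394 genes kept in both, 168 were higher and 107 lower at 0 mM in both tissues, where independent lists would share 11.6 and 9.14, and the changes correlated with r = 0.40 across genes, which are not independent replicates. At 100 mM 206 were higher and 112 lower in both (20.7 and 6.76 for independent lists, r = 0.42). Lsi1, Lsi2 and RCc3, root markers, stood in seedlings at 17.8 to 33.0% of their root level, so the seedling samples may hold root RNA. Part of the overlaps and correlations may then be root RNA measured in both tables, and no shared response of the tissues is read from them. In the opposite direction went 33 genes at 0 mM and 35 at 100 mM. The number that independent lists would give was not computed for this direction, so no excess is read from these counts. The changes of 152 genes at 0 mM and 235 at 100 mM differed by at least 2 on the log2 scale, which could not be tested without replicates. The widest named differences at 0 mM were Kiss Me Deadly 2 (log2 change -4.13 in roots and 0.07 in seedlings), a PB1 domain gene (Os11g0444700, -2.0 and 1.81), metallothionein 3B (0.36 and 3.57) and beta-amylase 6 (-1.24 and 1.94). At 100 mM they were WRKY76 (-3.11 and 2.19), pathogenesis-related 1a (-1.19 and 3.22), uclacyanin-like protein 29 (-0.18 and 4.07) and metallothionein 3B, listed at 0 in roots and at 96.4 against 6.65 FPKM in seedlings. Metallothionein 3B was low in roots, at 1.21 FPKM at 10 mM and 1.84 FPKM at 0 mM, so its differences rest on the seedling values.

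Some genes passed the threshold in the same direction at both nitrogen levels. In roots 52 genes were higher and 171 lower at both 0 and 100 mM, against 7.35 and 15.3 for independent lists, and 65 went in opposite directions. In seedlings 246 were higher and 124 lower at both, against 45.8 and 8.38, and 54 went in opposite directions. The changes correlated with r = 0.25 in roots and 0.43 in seedlings, below the 0.50 that a simulation of unchanged columns with equal noise gives for a shared control. The covariances were 0.061 and 0.14. The noise of a column is unknown, so no covariance or overlap could be simulated, and the control could not be split. Part of the overlaps may come from the shared column, and no shared response is read from them. NAS1, NAS2, YSL15 and IRO2 in roots and protochlorophyllide oxidoreductase A, ChlH and senescence associated gene 12-1 in seedlings were among the genes that moved the same way at both levels, whereas NIGT1, hydroxycinnamoyltransferase 4 and putrescine hydroxycinnamoyl transferase 2 moved in opposite directions in roots.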

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

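Of the tests in this part, those on the scaling of the columns within a tissue, on the share of leaf RNA, on the root markers alone and on the share of root RNA at 100 mM were chosen after the result was seen. For the others the prediction came first, although the correlations between the columns and the levels of the root markers were already known.

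Some named genes went in opposite directions in roots and seedlings by at least 1 on the log2 scale, which drew attention to them, and none of these differences was tested, since each tissue has 1 value per level. At 0 mM the change in roots minus that in seedlings was -2.97 for NRT1.1B (36.1 to 9.26 FPKM in roots, 22.1 to 49.1 FPKM in seedlings), -3.18 for beta-amylase 6 and -3.81 for the PB1 domain gene Os11g0444700. At 100 mM it was -5.30 for WRKY76 (11.8 to 0.475 FPKM in roots, 3.48 to 19.4 FPKM in seedlings), -3.73 for WRKY62, -4.41 for pathogenesis-related 1a, -4.05 for chitinase 1, -3.43 for pathogenesis-related gene 4 and -3.55 for flavanone 3-hydroxylase 2. The WRKY list lay below the random range in roots and above it in seedlings at 100 mM, its medians of -0.11 and 0.61 differing by -0.72.

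Light-harvesting genes were lower in seedlings at 0 and 100 mM than at 10 mM, by medians of -0.79 and -1.85, with 8 and 20 of 23 past the threshold. Scaling of the seedling columns is argued against at 100 mM, where the median was -2.06 after median-of-ratios rescaling and -1.03 after quantile normalization. At 0 mM the 2 scalings gave -0.89 and -0.17. The -0.89 argues against a single factor per column. Quantile normalization gives the highest values of all columns the same size, and this list holds the highest value of the 10 mM column (6666 FPKM). The -0.17 therefore cannot tell scaling from a fall of the highest genes. A scaling that acts on high values alone stays open at 0 mM. A smaller share of leaf RNA as the only cause is argued against at 100 mM, if Rubisco small subunit genes follow that share, which was not tested. There the lowest change of such a gene was -0.94, above the upper quartile of the light-harvesting list at -1.32, and a partial contribution stays open. At 0 mM a smaller share of leaf RNA stays open, since the lowest was -0.70, below that quartile at -0.60, and the other 2 were 0.29 and 0.47. For another time of day or light at harvest the rule set beforehand gave no answer: 2 of 11 core clock genes moved by at least 1 at 0 mM and 6 at 100 mM, among them, chosen after their values were seen, PRR95 from 95.3 to 10.7 FPKM and FKF1 from 31.0 to 5.01 FPKM, while 0 and 1 did so in roots. At 100 mM, however, 9 of 11 lay below their 10 mM level in roots (median -0.80), as in seedlings (median -1.16). Harvest times are not given in the sources used here, so another time of day or light at harvest and an effect of nitrogen cannot be told apart, and both stay open.

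Iron acquisition genes were lower in roots at 0 and 100 mM than at 10 mM, by medians of -2.74 and -2.68. If the 10 mM root column stood apart in general, it would be the odd column for many genes, but it was so for 17.5% of the 1276 root genes with a single column apart, against 44.8% for 0 mM and 37.7% for 100 mM. Scaling of the root columns is argued against too, since the medians after rescaling were -2.81 and -2.78. A response to both nitrogen levels is a candidate explanation, and a difference in iron supply to the 10 mM plants stays open. In seedlings the list was also lower at both levels, with medians of -0.63 and -0.42. That does not tell the 2 apart, and it may in part be root RNA in the seedling samples.

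Root marker genes moved in seedlings by medians of 0.28 at 0 mM and -0.18 at 100 mM, both inside the random range, with 0 of 6 past the threshold. At 100 mM 2 of 6 were lower after median-of-ratios rescaling (median -0.39) and 1 after quantile normalization (median -0.36). A changed share of root RNA in the seedling samples may contribute at 0 mM, since the seedling to root ratios of Lsi1, Lsi2 and RCc3 were 1.41 to 1.82 times those at 10 mM. Part of that rise came from lower root levels. From 10 to 0 mM, Lsi1 went from 709 to 467 FPKM in roots and from 126 to 151 FPKM in seedlings. Reading these ratios as a share assumes that roots in both kinds of sample express the genes alike, which was not tested. The lowest ratio in this test, 1.34 for silicon efflux transporter 4, adds nothing, because that gene and transporters 3 and 5 stood in seedlings at 91.5% or more of their root level at 10 mM and do not mark roots here. For 196 genes picked as root-enriched from the 100 mM columns alone, which include Lsi1, Lsi2 and RCc3, the median ratio at 0 mM was 1.31 times that at 10 mM (quartiles 1.06 and 1.59). Scaling between the tables is argued against, because the median over 20343 genes rose by 0.109 of that amount on the log2 scale. A smaller share of root RNA at 100 mM finds no support, since the ratios of the same 3 markers were 1.16 to 1.5 times those at 10 mM, but it is not excluded. The 196 genes stood at a median of 28.7% of their root level at 100 mM against 23.4% at 10 mM. They were picked by a level under 35% at 100 mM, so that value is no evidence on this share. For 238 genes picked as root-enriched from the 0 mM columns alone, the median ratio at 100 mM over that at 10 mM was 1.11 times that of all genes, with a lower quartile of 0.97. That share and changed expression outside the roots stay open.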

How the results depend on the processing

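Of the alternatives here, the restriction to features with a short name and quantile normalization for the gene lists and for genes moving the same way at 0 and 100 mM were chosen after the data were seen. No paired analysis was possible because the tables hold 1 value per group, so that replicate numbers do not reach the values. For the same reason the replicate block, limma without the trend, fits of 2 groups, leaving out libraries, an estimated correlation between genes and the pairing of adjusted p with fold change were not run. Unknown depth limits low genes most, and it shows in the pseudocount. The 14 totals (higher and lower genes together, tissue differences, genes moving the same way, lists outside the range) stayed within 1.5 times under both rescalings and without a filter, but the split of seedlings at 100 mM did not, with 892 higher and 688 lower after median-of-ratios rescaling. With a pseudocount of 5 the genes past the threshold numbered 465, 351 and 767 in roots (0 against 10, 100 against 10 and 100 against 0 mM) and 519, 801 and 766 in seedlings, and the genes differing between tissues 60 at 0 mM and 89 at 100 mM. With 0.1 they numbered 1433 for roots at 100 mM, 1883 for seedlings at 0 mM, 287 and 404 for the tissue differences, and 348 in roots and 713 in seedlings for genes moving the same way at 0 and 100 mM. A larger pseudocount shrinks the changes of low genes by construction. With a mean of at least 5 FPKM there were 561 and 1127 in roots at 100 against 10 and 100 against 0 mM, 1070 in seedlings at 100 against 0 mM and 116 for the tissue difference at 100 mM, with fewer genes counted. Restricting to features with a short name left 454, 366 and 722 in roots, 493, 762 and 664 in seedlings, and 63 and 115 tissue differences, again among fewer genes. Of 269 changes of named genes past the threshold, 190 stayed past it with a pseudocount of 5 and 260 after either rescaling. All 269 kept their direction under each of the 6 alternatives planned, but only quantile normalization could have reversed one. A pseudocount or a filter cannot change a direction, and the median-of-ratios shifts, at most about 0.21, are too small to. Of 90 list medians none moved by over 1.5 times with a pseudocount of 0.1 or after median-of-ratios rescaling, and 1 did without a filter, that of the defence list in seedlings at 100 mM (0.24, with members of low values added). After quantile normalization 3 did, all in seedlings: light harvesting at 0 mM (-0.17) and 100 mM (-1.03) and the leaf markers at 100 mM (-0.98), and the cause was not tested.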

Other observations

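The 3 lists described first, the look at the direction of the clock genes and the single genes named in this part were chosen after the data were seen, and no explanation was tested for them. In roots at 0 mM, 8 of 27 intrinsic protein aquaporins were lower and 1 higher (median -0.46, percentile 0), among them tonoplast intrinsic protein 2 (Os06g0336200) at 312 against 818 FPKM and plasma membrane intrinsic protein 1 (Os02g0823100) at 154 against 434 FPKM. In seedlings at 0 mM, 2 of 28 were lower and 3 higher (percentile 3.13), and plasma membrane intrinsic protein 2 (Os09g0541000) was at 869 against 384 FPKM. At 100 mM their medians were -0.15 in roots (percentile 0.760) and 0.02 in seedlings (percentile 23.6), the latter turning negative under rescaling. Metallothioneins were higher in seedlings at 0 mM (7 of 12, median 1.35, percentile 100), with metallothionein I-3A at 7915 against 2926 FPKM, while in roots at 100 mM 3 of 12 were lower, a median of -0.77 (percentile 0). In seedlings at 100 mM their median was 0.42 (percentile 99.6) and in roots at 0 mM 0.09.

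Genes named nitrate transporter had medians of 0.50 in seedlings at 0 mM (percentile 99.7), 0.34 in seedlings at 100 mM, 0.09 in roots at 0 mM and -0.12 in roots at 100 mM, the last 3 inside the random range. Nitrate transporter 1.3A was higher at 0 mM in both tissues, at 22.7 against 6.32 FPKM in roots and 22.9 against 8.65 FPKM in seedlings. Nitrate transporter 1.5B, with 0.256 FPKM in roots and 4.10 FPKM in seedlings at 10 mM, stood at 46.6 and 26.3 FPKM at 100 mM.

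Core clock genes at 100 mM lay below their 10 mM level for 9 of 11 genes in roots (median -0.80) and 9 of 11 in seedlings (median -1.16). At 0 mM 7 of 11 did so in each tissue, with medians of -0.06 and -0.25. LUX (Os01g0971800) in seedlings was at 255 FPKM at 0 mM, 108 at 10 mM and 43.0 at 100 mM, and LHY (Os08g0157600) at 3.48, 15.3 and 6.32 FPKM.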
